A study of Drosophila melanogaster with 2 samples.

How the data were processed

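ChIP-seq against GFP was carried out on embryos of Drosophila melanogaster, 0 to 24 h of age and of mixed sex, that expressed CG14962 (Asciz) fused to GFP at its C terminus. Chromatin was fragmented by sonication to 200 to 800 bp, per the labels. There was 1 group with 2 libraries, biological replicates 1 and 3, each of technical replicate 1. The labels call them biological replicates and give a separate biosample for each.

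The deposited files are peak lists in narrowPeak layout. Each library has a relaxed list of 30000 regions that holds peaks and background, a further relaxed list was made by the authors from both libraries together, and an optimal list holds the peaks the authors kept by the irreproducible discovery rate (IDR), a measure of how reproducible the rank of a peak is between replicates. Each list was deposited for the genome builds dm6 and dm3. Per the deposited file listings, both replicates' relaxed lists in dm6 were made against the same control alignment, which is not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. The signal column gives the peak caller's signal for each peak as deposited by the authors, on a scale that differs from list to list. The −log10 q value of each peak, as deposited by the authors, is shared by many peaks and was not used to rank them. Summits were taken from the deposited summit offsets. The signal is the authors' own value per peak and was used only to describe, rank and filter peaks within a list. No counts are in the files, so the depth of each library is unknown and no counting error can be given.

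The reproducible (IDR) list in dm6 was the main peak set. It was found to hold exactly the 5085 regions of highest signal in the pooled list, in 5078 distinct intervals, of which 7 carried 2 summits. To set libraries side by side, the signal of the strongest overlapping region (at least 1 bp) in each replicate list was divided by that library's median over the reproducible peaks, and is called the relative signal. Coordinates are 1-based in dm6. Genes came from Ensembl release 115 (BDGP 6.54), without transposable elements, and sequence from the release 6 assembly. All peak ends lay within the assembly's chromosome lengths. Only 2L, 2R, 3L, 3R, 4 and X were used. Annotation in dm3 was not used here, and dm3 lists served only for counts, ratios and overlaps.

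Summits were assigned once each, in the order promoter (within 500 bp of any TSS), 5' untranslated, coding, 3' untranslated, other exon, intron and intergenic, and compared with 1000 random placements within chromosomes by a two-sided permutation test, whose smallest p is 0.002. Chromosome counts were compared with assembled length by exact binomial tests. A gene was called bound when a summit lay within 500 bp of one of its TSSs. The 16 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and tRNA genes with all other non-coding genes except pseudogenes, which is how the planned comparison within a biotype class was read. Symbols were matched exactly or through a single synonym, and 12 lists gave as many genes as symbols. The DNA damage list gave 47 genes from 48 symbols, the insulator list 19 from 21, the polycomb and trithorax list 26 from 27 and the RNA polymerase II list 32 from 34. A gene named by 2 symbols, as in the RNA polymerase II list, was counted once. Each list was also ranked among 10000 random lists matched on the number of TSSs within 10 kb in 10 classes. Canonical 6-mers and 8-mers in the 101 bp round each summit were compared with 2 windows of the same size centred 300 bp away, and then with the TSSs of promoters with no summit within 1 kb. Adjusted p-values are by Benjamini-Hochberg, with a threshold of 0.05. Peaks, genes and k-mers are not independent replicates, so these p-values describe this peak list and not the variation between embryos. Bootstrap intervals used 1000 resamples of peaks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

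Calculations were tested on simulated data. With 5085 random positions, no 8-mer of 32896 was called, and an 8-mer planted in 1% of the windows ranked first. For the location test on 5085 summits, planted promoter summits gave 38.4% where 38.8% had been set. For the gene lists over 18164 genes, 5 of 100 random bindings called any list, and the insulator list set to 50% was called in 83 of 100. For replicate overlap over 5085 regions, 80.2% were recovered where 79.7% were shared. Some real k-mer and list values had been looked at before these tests were written, and no calculation needed changing after them.

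Named genes were chosen by a rule set before the data were examined: Asciz and ctp whatever their value, the 15 highest reproducible peaks with the gene of the nearest TSS, the 3 bound members of highest signal in each list, the 5 highest peaks with no TSS within 2 kb, and the 10 leading k-mers by p. Of the genes this rule picks, 1 is not reported here. Names outside it (the other bound members of the insulator list, ph-d, tim, the nearer genes RpL13, RpL17 and CG30122, and the most depleted 8-mer) were chosen after their values were seen. Alternatives covered promoter windows of 200 and 1000 bp, stricter peak sets, other overlap rules, other backgrounds, sequence windows of 25 and 100 bp, the dm3 lists and each library alone. Shuffled windows and the distal summits were added after the data were seen.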

Results

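Binding of Asciz was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after egg laying. Asciz, also listed as CG14962, is a zinc finger transcription factor whose known target is ctp, the gene for the dynein light chain LC8. The flies carried a transgene that makes Asciz with GFP at its C terminus, and an antibody against GFP was used for the precipitation. There was 1 group of 2 libraries, biological replicates 1 and 3. The values were the authors' peak lists, so the number of reads behind each library is unknown here. No second condition was present, and the comparisons below are therefore between peaks, between the 2 libraries and between bound sites and the rest of the genome.

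The first question was where Asciz was bound most strongly. The ctp promoter carried by far the highest peak. Its pooled signal was 26348, which was 10.2 times that of the next peak (2586) and 128 times the median over all peaks. Set against the median peak of each library, the ctp peak stood at 112 in replicate 1 and 129 in replicate 3 (mean 121 ± 12.5, SD, n = 2), and it ranked first in both. The peak spans X:4687382-4688791 in dm6, with its summit at 4688080, 123 bp upstream of the nearest annotated transcription start site (TSS) of ctp (FBgn0011760, X:4687800-4702034, plus strand). The 101 bp centred on the summit, X:4688030-4688130, read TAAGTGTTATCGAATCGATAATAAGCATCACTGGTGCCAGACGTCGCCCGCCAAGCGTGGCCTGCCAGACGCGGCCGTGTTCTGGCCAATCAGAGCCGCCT on the plus strand. At the tagged gene itself, Asciz (FBgn0035407, 3L:3163786-3166250, minus strand), no summit of any dm6 list lay within 10 kb of the 5' end, and the nearest reproducible summit was 24.7 kb away.

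**Figure D1:**
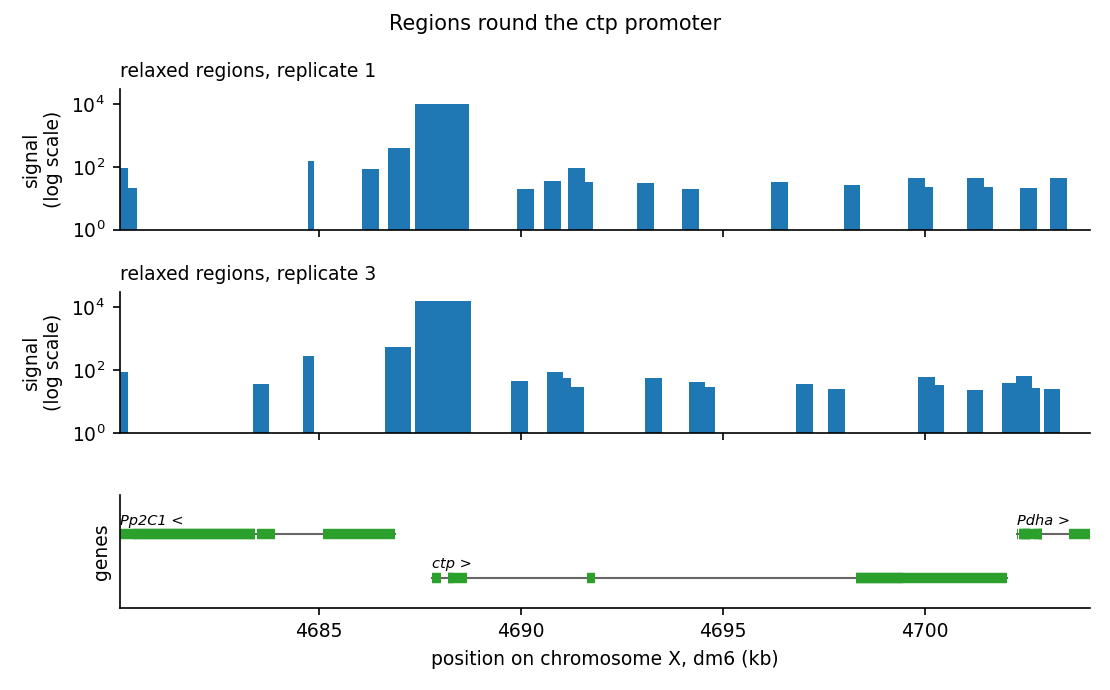
Regions round the ctp promoter in the relaxed list of each replicate, drawn on chromosome X (dm6, kb) with the peak caller's signal on a log axis, above the annotated genes (exons green, arrows giving the strand). The region at the 5' end of ctp reached 10234 in replicate 1 and 15988 in replicate 3.

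After ctp, the 14 next highest peaks had pooled signals between 1633 and 2586. The second lay in an intron at CG11050 (2L:6612498-6612903, signal 2586, 1017 bp downstream of the nearest TSS), and the third at the TSS of lncRNA:CR31840 (2L:14023901-14024359, 2490). Promoter peaks followed at Ugalt, a UDP-galactose transporter gene (X:2703696-2704073, 2396), at px (2R:22514119-22514495, 2180), at CG14100 (3L:19590428-19590805, 2094), at CG18549 (1921), at mRpL41, a mitochondrial ribosomal protein gene (2R:15217575-15217947, 1840), at PNPase (1660) and at Fkbp14 (1633). The peaks at cno (1838), Trl, the GAGA factor gene (1800), and sbb (1700) lay in introns. The peak nearest to cbt (2106) lay 1367 bp upstream of it, in an intron of another gene, and that at lncRNA:CR44619 (1904) in an exon 550 bp upstream of the nearest TSS. Relative signals at these 14 peaks ranged from 6.56 at Fkbp14 to 11.4 at CG11050 in replicate 1, and from 7.58 at lncRNA:CR44619 to 12.6 at CG11050 in replicate 3. Of the peaks with no TSS within 2 kb, the highest was that in sbb, 20115 bp from the nearest TSS (2R:18336875-18337350). It was followed by intergenic peaks nearest to CG13323 (2R:13035162-13035506, 1617) and CG31668 (2L:2202222-2202581, 1553), and by intronic peaks nearest to Lrch (1485) and Hr3, a nuclear receptor gene (1466).

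The authors' list of reproducible peaks held 5085 peaks in dm6, the regions of highest signal in the pooled list. The name is that of the list and does not mean that each peak was found in both libraries. The peaks had a median width of 424 bp and a median signal of 205 (quartiles 156 and 315). They covered 1.85 Mb, or 1.39% of the assembled sequence of the 6 chromosomes considered. Chromosome 4, the small and largely heterochromatic autosome, held 20 peaks, 0.395 of the number its length would give (adjusted p = 8.1e-06, exact binomial test, two-sided, Benjamini-Hochberg over 6 chromosomes). Chromosome arms 2L (984 peaks, 1.10 of expectation, adjusted exact p = 0.0022) and 3L (1167, 1.10, adjusted exact p = 0.0015) held more than their length would give. Arms 2R (893, 0.928, adjusted exact p = 0.016) and X (823, 0.921, adjusted exact p = 0.014) held fewer, and 3R (1198, 0.982, adjusted exact p = 0.49) did not pass the test. Expectation rested on length alone, with no allowance for the dose of X in embryos of mixed sex or for TSS density. Among the highest 25% of peaks by signal, neither the chromosome 4 nor the X deficit passed (adjusted exact p = 0.13 and 0.28). With fewer peaks tested, the log2 ratios to expectation there were -1.08 for chromosome 4 and -0.123 for X, against -1.34 and -0.118 for all peaks.

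The second question was how closely the 2 libraries matched. The strongest sites were shared. The region at ctp ranked first in both, and 79 of the top 100 regions of replicate 1 overlapped one of the top 100 of replicate 3, against a mean of 0.01% after circular shifts of the regions along the chromosomes. The share was 84.7% for the top 300, 82.8% for the top 1000, 79.7% for the top 3000 and 70.0% for the top 10000, where the shifts gave 0.217%, 0.396%, 1.54% and 5.54%. Of the 5085 reproducible peaks, 4910 (96.6%) overlapped some region of replicate 1 and 5080 (99.9%) some region of replicate 3. Within the top 5085 regions of a library, 84.8% were found in replicate 1, 88.7% in replicate 3 and 75.4% (3833 peaks) in both. These peaks are the strongest regions of a list pooled from the same 2 libraries, so their overlap with each library is partly built in. No chance value was computed for it, and 180 peaks lacked a region in at least 1 library.

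Single promoter peaks differed between the libraries. Cp190, an insulator protein gene (3R:15275217-15275479), had a relative signal of 0.793 in replicate 1 and 3.34 in replicate 3, and the promoter peaks of brm, bgcn and dup overlapped no region of replicate 1. Relative signals differed by more than 1 on the log2 scale at 212 peaks (4.32% of the 4905 with a region in both), with a median absolute difference of 0.27. Among promoter peaks 115 of 1768 differed by that much (6.5%), and among the others 97 of 3137 (3.09%). These counts leave out the 180 peaks that lacked a region in a library, of which 134 were promoter peaks and 46 were others. Across peaks, which are not independent replicates, Spearman's rho between the libraries was 0.776. It was 0.803 among the 2542 stronger peaks and 0.0443 among the 2543 weaker ones, which span a narrow range of pooled signal by construction.

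**Figure D2:**
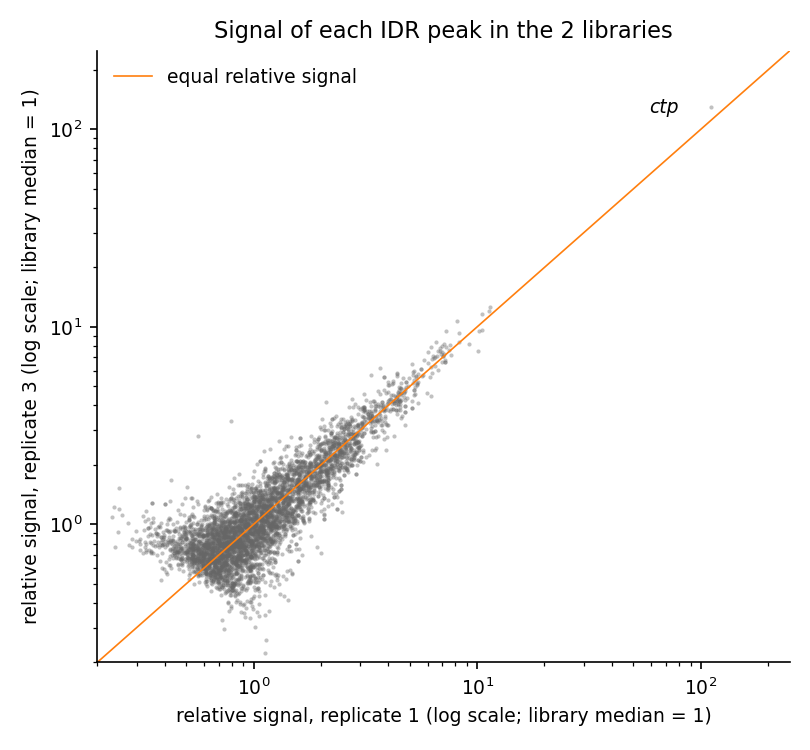
Relative signal of each reproducible peak (signal divided by the library's median over these peaks) in replicate 1 (x axis) and replicate 3 (y axis), both on log axes, with the line of equal values. The ctp peak lies at 112 and 129, above the next highest peaks at 11.4 and 12.6.

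The third question was which parts of the genome the summits lay in. Promoters, taken as 500 bp either side of any annotated TSS, held 1902 summits or 37.4% (95% Wilson interval 36.1 to 38.7), against 13.6% when the summits were placed at random within their chromosomes, a 2.75-fold excess. Coding sequence outside promoters held 9 summits, 0.177% against 13.7% at random. Introns held 45.1% against 39.3%, intergenic sequence 14.5% against 27.4% and 3' untranslated regions 1.04% against 4.38%. Each of these 5 departures had an adjusted permutation p of 0.0028 over 7 classes (0.002 unadjusted, the smallest that 1000 placements can give). The 5' untranslated regions outside promoters did not pass (0.649% against 0.774%, adjusted permutation p = 0.35), and other exons did (1.12% against 0.82%, adjusted permutation p = 0.035).

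Promoter peaks were concentrated at the top of the list. They made up 54% of ranks 1 to 500 and 46% of ranks 501 to 1000, and between 31.6% and 36.4% in each later set of 500. The promoter excess was present in each library alone, with 35.0% in the top 5085 regions of replicate 1 and 40.4% in those of replicate 3. Against the authors' weaker pooled regions outside the reproducible peaks, of which 20.9% lay in promoters, the intron direction turned: 45.1% of peaks and 49.4% of the weaker regions lay in introns (adjusted exact p = 4.8e-08, Fisher's exact test). The classes are parts of a single total, so the larger promoter share of the peaks leaves less for introns. This turn therefore does not show that the peaks avoid introns.

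**Figure D3:**
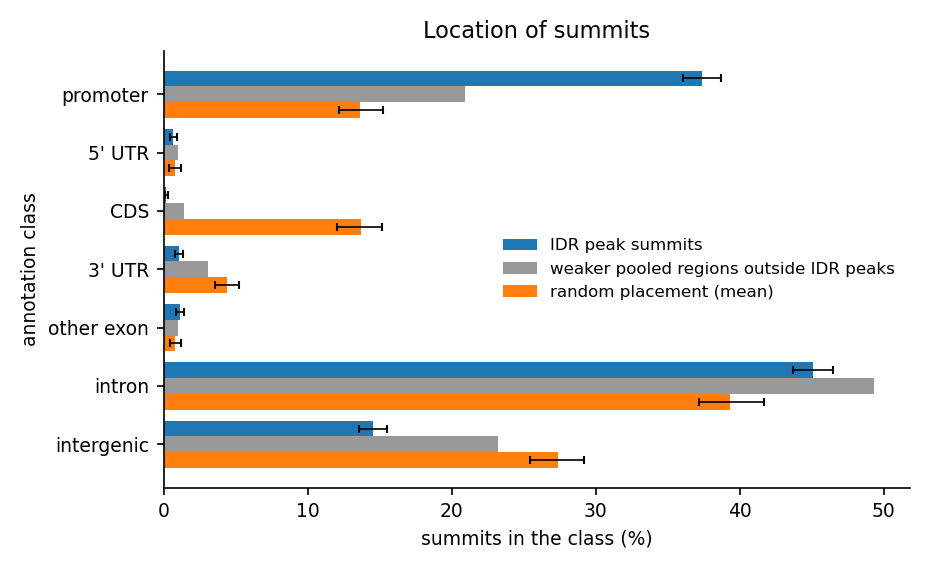
Share of summits (x axis, %) in each annotation class (y axis) for the 5085 reproducible peaks with 95% Wilson intervals, for weaker pooled regions outside them, and for 1000 random placements (bar, mean; whiskers, lowest and highest placement). Promoters hold 37.4% of peak summits, 20.9% of weaker regions and 13.6% of random positions.

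Within promoters the summits sat mainly upstream of the nearest annotated TSS. That TSS can lie inside a gene: the summits at ctp, px, PNPase and Fkbp14 fell within the annotated span of the gene. The median position was -123 bp from the nearest TSS (95% bootstrap interval over peaks -131 to -115 bp), and 75.4% of the 1902 summits were upstream. The top regions of replicate 1 gave -140 bp and those of replicate 3 gave -104 bp, so the interval over peaks is narrower than the difference between libraries. The quartiles were -236 and -3 bp. Among the 15 highest peaks, the promoter summits besides ctp lay at -196 bp (px), -136 bp (mRpL41), -131 bp (Fkbp14), -113 bp (CG18549), -91 bp (CG14100), -79 bp (PNPase), -41 bp (Ugalt) and 10 bp downstream (lncRNA:CR31840). Of the promoter summits, 489 (25.7%) lay within 500 bp of TSSs on both strands, so that the gene they belong to is open.

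The fourth question was which groups of genes had bound promoters. Genes for the cytosolic ribosomal proteins had the highest share of the 16 lists: 70 of 93 (75.3%, 95% Wilson interval 65.6 to 82.9) had a summit within 500 bp of a TSS, against 13.3% of other protein-coding genes (adjusted p = 3.6e-40, Fisher's exact test, two-sided, Benjamini-Hochberg over 16 lists) and a median of 16.1% in random lists matched on TSS density. The highest of them were RpS27 (3R:25247348-25247679, signal 921) and RpL7 (2L:10200906-10201166, 750), with relative signals of 4.34 ± 0.168 and 3.42 ± 0.586 (SD, n = 2). The median signal of the 70 was 329, against 237 for other bound protein-coding genes, and their median summit lay at -14 bp. In the top regions of replicate 1 alone 56 of the 93 were bound (60.2%, against 12.5% of other genes). In those of replicate 3 alone 74 were bound (79.6%, against 14.8%). The replicate 1 share lies outside the Wilson interval, which covers spread over genes and not between libraries. Genes for insulator and promoter architectural proteins were the other list to pass, with 8 of 19 bound (42.1%, adjusted exact p = 0.018, Fisher's exact test). They were led by Chro, the chromodomain protein Chromator (3L:22878728-22879081, signal 1541), Cp190 (747) and Dref (576), and included M1BP, lola, Trl, BEAF-32 and CTCF. The Dref summit is shared with the ribosomal protein gene RpL13, whose TSS is nearer (-15 bp, against -69 bp for Dref). The log2 odds ratio of this list was 2.22. The call was lost with a promoter window of 1000 bp (8 of 19, 1.86, adjusted exact p = 0.064) and when each summit was given only to its nearest TSS (6 of 19, 2.02, adjusted exact p = 0.062).

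Several lists lay above other genes without passing the test. Muscle genes had 7 of 19 bound (36.8%, adjusted exact p = 0.054), led by Msp300 (signal 560), sls (373) and Act87E (239), and passed with nearest TSSs only (log2 odds ratio 2.34 in place of 1.92, adjusted exact p = 0.020). With a 200 bp window 3 of 19 were bound (1.19, adjusted exact p = 0.45). Polycomb and trithorax group genes had 8 of 26 (30.8%, adjusted exact p = 0.063), led by ph-p (X:2137177-2137532, 1583), brm (559) and E(z) (519). The ph-p and ph-d genes are near-identical neighbours, and their assignment is uncertain. Of the RNA polymerase II and general transcription factor genes, 8 of 32 were bound (25%, adjusted exact p = 0.16), with Polr2B (400), Taf2 (309) and Polr2F (212) highest. Transfer RNA genes had 33 of 290 (11.4%) against 7.18% of other non-coding genes (adjusted exact p = 0.057), with tRNA:Tyr-GTA-1-8 (906), tRNA:Phe-GAA-1-2 (332) and tRNA:Gly-GCC-1-9 (320) highest. The last 2 of these summits lay nearer to the TSSs of RpL17 and CG30122. When each summit was given only to its nearest TSS, 16 of 290 tRNA genes were bound (5.52% against 5.0%, log2 odds ratio 0.19 in place of 0.75, adjusted exact p = 0.83). With a 200 bp window 18 were bound (6.21% against 3.11%, 1.07, adjusted exact p = 0.051). They are multicopy genes, so single members are uncertain, and among the 2542 stronger peaks the direction turned (3.45% against 4.07%, adjusted exact p = 0.81).

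The remaining lists did not differ from other genes by the test. Among heat shock genes 5 of 23 were bound (adjusted exact p = 0.42), with Hsp27 (3L:9383757-9384042, signal 978), Hsp83 (834) and Hsc70-5 (430) highest. That list passed in the top regions of replicate 1 alone (adjusted exact p = 0.037). Mitochondrial ribosomal protein genes had 10 of 73 (13.7%, adjusted exact p = 1), although mRpL41 (1840), mRpS23 (1567) and mRpS10 (1510) were among the highest peaks. Besides ctp, the dynein and dynactin list had only Lis-1 (signal 157) and Dlc90F (139) bound among 20 genes (adjusted exact p = 0.94). In the DNA damage list 7 of 47 were bound (adjusted exact p = 0.95), with Rrp1 (372), spn-B (323) and p53 (312) highest; its member tim is the clock gene. Cell cycle regulators had 6 of 33 (Dp, 407; E2f1, 211; dup, 207; adjusted exact p = 0.71), and germline and piRNA genes 3 of 20 (bgcn, 432; cuff, 261; piwi, 150; adjusted exact p = 0.94). Gut, fat body and hemocyte genes had 3 of 21 (fkh, 702, Hnf4, 385 and GATAe, 208, adjusted exact p = 1) and neuronal genes 2 of 23 (elav, 903 and moody, 420, adjusted exact p = 0.94). The lowest shares were those of proteasome genes, 2 of 48 (Prosbeta2, 210 and Rpn11, 142, adjusted exact p = 0.15), and of segmentation and Hox genes, 1 of 30 (bcd, 140, adjusted exact p = 0.23). Of the summits named for list members, those of mRpS23, mRpS10, Rrp1, Dlc90F, dup, elav, cuff, piwi, brm and Taf2 lay as near or nearer to the TSS of a gene outside the list.

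**Figure D4:**
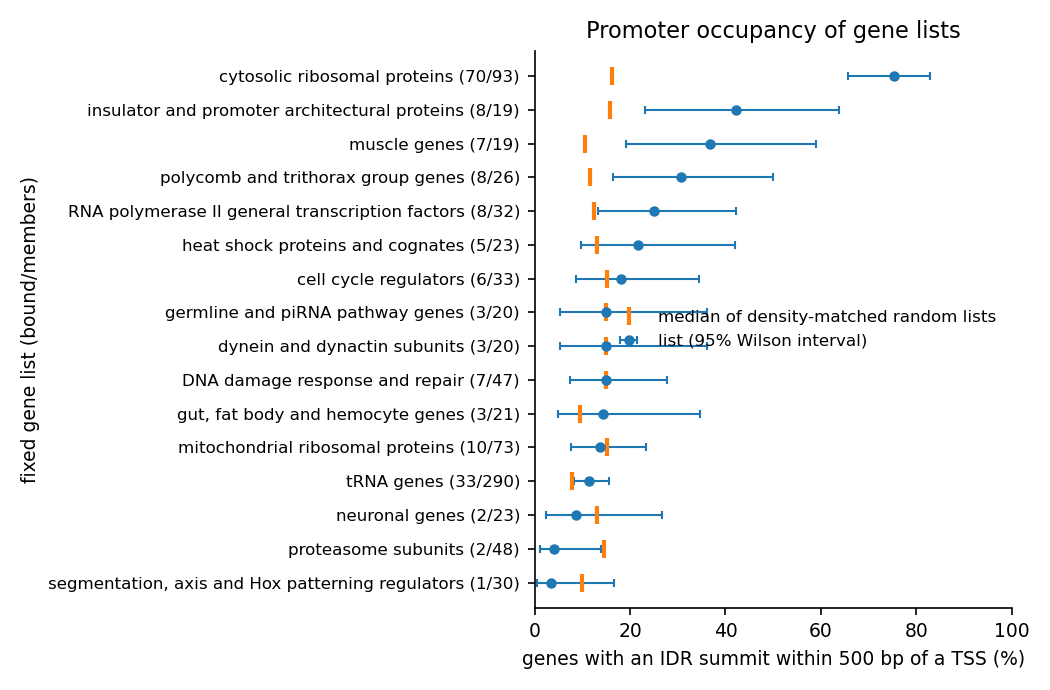
Share of genes in each list with a peak summit within 500 bp of a TSS (x axis, %; points with 95% Wilson intervals) and the median of 10000 random lists matched on TSS density (orange bars). Cytosolic ribosomal protein genes lie at 75.3% against a matched median of 16.1%.

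The fifth question was whether a sequence was centred at the summits. The summit windows of 101 bp were rich in A and T, 66.3% ± 8.77 (SD over 5085 windows) against 56.8% ± 9.69 in windows 300 bp to either side. The same held for summits in promoters (66.0% against 56.8%, and 57.0% at the TSSs of unbound promoters) and for intronic and intergenic summits more than 2 kb from a TSS (66.5% against 56.5%). The windows of CG11050 (77.2%) and sbb (66.3%) were of this kind, and that of ctp was not: at 41.6% A+T, it was undercut by 25 of the other windows (0.492% of all). The unbound promoter windows were centred on the TSS and not on a summit, so that contrast does not separate binding from position in the promoter.

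The 10 leading 8-mers were made of A and T, or of A and T with a single G or C. AATATTTA was present in 6.51% of summit windows and 1.96% of flanking windows, a 3.33-fold excess (adjusted p = 1.6e-39, Fisher's exact test, two-sided, Benjamini-Hochberg over 32896 8-mers). It was followed by AAATATAT (3.02-fold), AATATTTG (3.70-fold), AAATATTT (2.92-fold), TTTAAAAA (2.84-fold), ATATTTAA (3.31-fold), AATAAATA (2.38-fold), ATATTAAA (3.54-fold), ATTTAAAA (2.80-fold) and ATATTTAC (4.12-fold). In all, 2020 8-mers were more frequent at summits than in flanks and 2003 less frequent, and for 6-mers the counts were 538 and 1076 of 2080. Against shuffled summit windows with the same dinucleotide counts, a background chosen after the data were seen, 402 8-mers were higher and 95 lower. AATATTTA kept a 2.18-fold excess there (adjusted exact p = 2.4e-19), AATATTTG a 2.85-fold and AAATATTT a 2.77-fold one. Of the 10 leading 8-mers, 4 did not pass against shuffles: TTTAAAAA (1.0-fold, adjusted exact p = 1), ATTTAAAA (1.08-fold, 0.82), ATATTAAA (1.18-fold, 0.51) and ATATTTAA (1.32-fold, 0.054). Against unbound promoters, 985 8-mers were higher at promoter summits and 196 lower, and AATATTTA stood at 5.36% against 1.80% (adjusted exact p = 1.1e-15). The unbound windows were centred on the TSS and the bound ones on summits, at a median of -123 bp. This comparison therefore does not separate binding from position in the promoter. Of the most depleted 8-mers, GCAGCAGC, a repeat common in coding sequence, was found in 0.295% of summit windows and 1.82% of flanks (adjusted exact p = 2.2e-15).

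**Figure D5:**
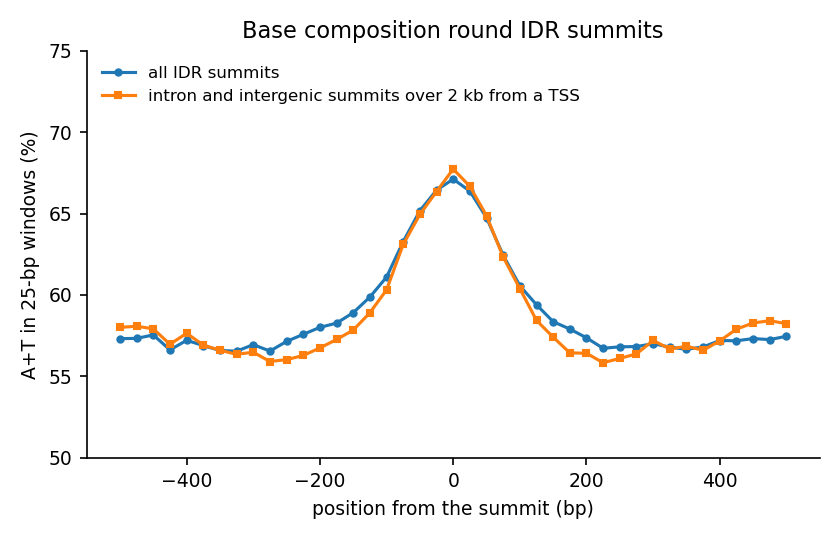
Mean A+T content in 25-bp windows (y axis, %) by distance from the summit (x axis, bp) for all 5085 reproducible peaks and for the 1857 intronic and intergenic ones more than 2 kb from a TSS. Both curves are highest at the summit, at 67.1% and 67.7%, and fall to 57.4% and 56.4% at 200 bp and 58.0% and 56.7% at -200 bp (plus-strand coordinates).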

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

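Of the main results, 58 values under the alternatives kept their direction and side of the threshold, moved by less than the spread or, for counts, changed by at most 1.5-fold, 15 moved, 4 lost their call and 1 reversed. Of the single gene lists, 86 stayed, 2 lost and 2 gained a call and 6 reversed. Causes were not tested unless named. The X deficit (log2 of observed over expected) lost its call among the upper 50% of peaks (-0.11, adjusted exact p = 0.10) and the highest 25% (-0.12, 0.28), as did chromosome 4 in the highest 25% (-1.08, 0.13), where fewer peaks were tested. The share of peaks in the top regions of both libraries was 61.9% with 50% reciprocal overlap, 69.1% with summits within 100 bp and 94.5% at 2 times the rank depth. With each library alone it was 84.8% to 88.7%, and the ctp ratio 9.76 to 10.3. The intron excess (log2) lost its call with a 1000 bp promoter window (0.046, adjusted permutation p = 0.086) and reversed against weaker pooled regions (-0.13). The median summit position was -80 bp with a 200 bp window, which excludes farther summits. With a 1000 bp window 1 list passed, the ribosomal one. List odds ratios (log2) reversed, none past the threshold, for gut, fat body and hemocyte genes with 200 bp (-2.0), mitochondrial ribosomal genes with 1000 bp (-0.15) and nearest TSSs (-1.27), and, in the upper 50% of peaks, dynein (-0.21), neuronal (0.39) and tRNA genes (-0.19). The 8-mers above background numbered 786 with 25 bp windows, 2880 with 100 bp windows, 1048 in the upper 50%, 985 against unbound promoters and, in tests added after the data were seen, 402 against shuffles and 626 at distal summits (155 lower). The A+T difference was 7.66 percentage points with 100 bp windows and 11.0 in the upper 50%. Depth is unknown, so a weak or missing region in 1 library cannot be read as absence of binding.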

Other observations

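The gene families, sequence elements, G- and C-containing 8-mers and ctp window below were chosen after the main results were seen, as were the tests of one library alone, of shuffled weaker windows and of gene lists matched on density with nearest TSSs only. Grouping protein-coding genes by the letters of their symbols gave 81 families of at least 10 genes, of which 3 were bound above and 5 below other genes (Fisher's exact test, Benjamini-Hochberg). The higher ones were RpL (37 of 50), RpS (28 of 38) and Tsp, the tetraspanins (12 of 35, 34.3% against 13.7% of other genes, adjusted exact p = 0.020). The lower ones were the chemoreceptor families Gr (0 of 60, adjusted exact p = 0.0037), Ir (0 of 60, adjusted exact p = 0.0037) and Or (0 of 59, adjusted exact p = 0.0051), the cytochrome P450 genes Cyp (3 of 85, adjusted exact p = 0.038) and the histone genes His (1 of 115, adjusted exact p = 4.5e-05), which are multicopy and therefore uncertain.

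Of the 8-mers above flanks, 199 were also above shuffled windows, and 56 of these held at least 3 G or C bases, of which 11 were also above unbound promoters. The 4 named here were picked by eye among these 56, and 3 of them because they resemble known binding cores, so they do not represent the set. TGCAAACA and AGCAAACA, which share the core bound by forkhead factors, were present in 1.91% and 2.60% of summit windows against 0.787% and 1.37% of flanks (adjusted exact p = 5.3e-07 and 1.2e-05), and were also above unbound promoters (2.66-fold and 2.0-fold). ACCGGAAA, which holds an ETS-type core, was 3.73-fold above flanks, 4.82-fold above shuffles and 4.79-fold above unbound promoters (adjusted exact p = 3.2e-06). CACTGAGA was 3.93-fold above flanks and 8.46-fold above shuffles, but not distinguishable from unbound promoters (1.32-fold, adjusted exact p = 0.84). Of 8 known elements tested, 2 of broadly active promoters were rarer at bound than at unbound promoters: the Motif 1 core GGTCACAC was found at 0.946% of promoter summits and 3.78% of unbound promoters (adjusted exact p = 8.5e-13), and the DRE core TATCGATA at 2.05% and 3.73% (adjusted exact p = 0.00015), although it was above the flanks (0.944% against 0.344%, adjusted exact p = 1.1e-05). TATAAA was more frequent at promoter summits (22.9%) than at unbound promoters (15.9%, adjusted exact p = 2.4e-13). The GAGA element GAGAGAGA was above unbound promoters (1.31% against 0.582%, adjusted exact p = 0.0012) but below the flanks (0.885% against 1.81%, adjusted exact p = 1.1e-05). The E-box CAGCTG was below both (4.0% against 7.36% of unbound promoters, adjusted exact p = 1.4e-08). The CA repeat and the CT-rich element were below the flanks only (adjusted exact p = 6.0e-16 and 0.035), and the Zelda site CAGGTAG differed from neither (adjusted exact p = 0.90 and 1). Summit and TSS windows sit at different places in a promoter, which these shares do not separate. Base composition differs too (promoter summits 66.0% A+T, their flanks 56.8%, unbound TSSs 57.0%), and these shares do not correct for it. Against shuffles of the same windows, the CA repeat in its other phase, ACACACAC, was 5.31-fold more frequent (adjusted exact p = 4.6e-16). Shuffling breaks up repeats, so this does not show an enrichment at summits. Against real flanks the CA repeat CACACACA was depleted (1.79% against 4.25%).

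Of the weaker pooled regions outside the reproducible peaks, the 4550 within the first 10000 of the pooled list were also looked at, a set chosen after the peak list had been seen. Of these, 30.6% had their summit within 500 bp of a TSS, against a mean of 13.6% and a highest value of 15.3% over 1000 random placements, and coding sequence held 0.308%. Their summit windows held 63.5% A+T against 57.6% in the flanks. They included the promoters of 3 of the 23 cytosolic ribosomal protein genes with no reproducible summit.

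The ctp window held 41.6% A+T, against 57.4% to 80.2% at the next 14 peaks. Its 8-mers GCCAGACG and TGCCAGAC each occurred 2 times, and they overlap within a single repeated stretch. Of the reproducible peak windows, 69.6% had fewer repeated 8-mers, so the number of them alone was not rare. Only 0.492% of those windows had a lower A+T, so they are not matched to the ctp window in composition. GCCAGACG was in 12 summit windows and 21 flanking windows in all (0.236% against 0.206%, adjusted exact p = 0.89, Fisher's exact test), and TGCCAGAC in 13 and 39 (0.256% against 0.383%, adjusted exact p = 0.49).

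The ctp peak stood 10.2-fold above the next peak. A single library was argued against, since the lower of the 2 ratios was 9.76. Several copies of the leading 8-mer, AATATTTA, were argued against too, with 0 copies within 250 bp of the summit. The median over the 100 next strongest peaks was also 0, so this outcome was the usual one. It does not bear on copies of any other sequence in the ctp peak. Extra copies of the wider ctp region were not borne out: 26 pooled regions lay 2 to 20 kb from the summit, at the 90.2 percentile of other peaks, under the bound of 95 set beforehand though above the median of 13. Most sites meet that bound, so meeting it says little against such copies. A gain confined to the peak interval was not tested and may remain, and a direct effect of Asciz on this promoter was not tested either.

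The weaker 2543 peaks could be open chromatin with no sequence determinant. Any of the 10 leading 8-mers, chosen in the stronger peaks, occurred in 26.7% of the weaker windows and 12.9% of their flanks, a ratio of 2.07 (95% interval 1.88 to 2.28), which meets the bound set beforehand against it. That bound was set without regard to base composition, which differed (65.2% A+T at weaker summits, 57.1% in flanks), so once the value had been seen a shuffle ratio with its lower limit over 1.5 was also required. Against shuffles of the same windows the ratio was 1.43 (1.31 to 1.56). All of this interval lay above the limit set for composition alone, but it did not meet the limit set for more than composition. Shuffling keeps dinucleotide counts but breaks up longer runs and repeats, and no comparison of the flanks with their own shuffles is given. The ratio therefore does not decide whether composition was the only source of the excess in the weaker windows. A+T-rich open chromatin and binding to such sequence cannot be told apart for these peaks without a control track or an accessibility measurement.

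Background at the most transcribed genes may contribute to the promoter peaks. Cytosolic ribosomal protein genes were above all 10000 matched random lists and tRNA genes at the 98.1 percentile, as the test set beforehand required, but with nearest TSSs only the tRNA genes fell to the 59.7 percentile (16 of 290 bound), so the test does not decide. Among other lists, muscle genes were at the 99.4 percentile, polycomb and trithorax genes at 98.7 and proteasome genes at 0.99. The lists differ in size and were not ordered by expression, so these positions do not bear on background at transcribed genes. Ribosomal protein summits lay at a median of -14 bp, and those of all promoter peaks at -123 bp. Expression was not analysed here, so this explanation stays open beside specific binding, and no biological explanation was tested.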
